A study of Homo sapiens with 12 samples.

How the data were processed

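Total RNA, prepared with Trizol, came from 3 human cell lines of activated B cell-like diffuse large B cell lymphoma (ABC-DLBCL) under 4 treatments, and 150 ng of it was turned into biotin-labelled cRNA for each of 12 Affymetrix arrays. The deposited values are on a log2 scale, and the authors made them with RMA in Affymetrix Expression Console 1.1, which corrects background, quantile-normalizes the arrays and summarises probes into probe sets. The probe library and genome build behind the probe sets are not given in the sources used here, so no positions are printed. The table held 49386 probe sets for each array, with no missing value, and it was used on the log2 scale as deposited.

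Gene symbols came from the array's annotation, and 99.82% of them matched the reference gene table. Of the probe sets, 45253 carried 1 gene, 1327 several and 2800 no named gene, and only the first kind entered the comparisons. A further 6 are the array's control probe sets that carry 1 gene, and were left out with the other controls. Each gene was represented by its probe set with the highest mean level over the 12 arrays. A gene was tested when that probe set was above the 40th percentile of all values, a log2 level of 4.20, in at least 3 arrays. This left 13120 of 18239 genes, and the reported comparisons leave out the other 5119. Among the probe sets chosen, 1721 had names ending in x_at and 2336 names ending in s_at, which mark probes shared between transcripts. Of the genes fixed in advance to be reported, IRAK4 and CCL4 had no probe set of their own, and CYP1A1 was below the filter with a mean log2 level of 3.84.

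All 12 arrays were fitted together with limma 3.58.1 in R 4.3.3, with the data.table package (1.17.8), using treatment and cell line as terms (lmFit, contrasts.fit, eBayes with defaults). The cell line is the replicate, so each group has n = 3, and the fit had 6 residual degrees of freedom and a prior of 3.66. The 5 comparisons were CPI203, IRAKi and Combo each against Control, and Combo against each single treatment. A further contrast, Combo minus CPI203 minus IRAKi plus Control, measured the departure from additive log2 changes and is called the interaction term. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over the genes tested, and a gene was called at an adjusted p below 0.05. Standard errors (SE) are the moderated ones of this fit. Changes in a single line are 1 array against 1 array and were not tested.

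Before the data were examined, 26 gene lists were written from general knowledge and tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists within each comparison. Camera with a correlation estimated from the data and fry were run beside it. Members of a list were counted as risen, fallen or not past the test over all genes tested, and again adjusted over the list alone. Genes to be named were fixed at the same time. They are the 10 highest and 10 lowest log2 changes among called genes that moved one way in all 3 lines, up to 4 members of each called list in the list's direction and up to 2 in the other, and a fixed set of BET, MYD88 and NF-kB pathway, apoptosis and cell cycle genes. The examples printed are drawn from these, and any other gene named is stated to have been chosen after its values were seen.

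Correlations between treatment effects are Pearson's r and Spearman's rho across genes, which are not independent replicates. Where both contrasts use the same Control arrays, the correlation was set beside 100 simulations of unchanged groups that share the controls. The precision of each value is limited by the number of arrays. In data with planted changes, the test found 14.93% of genes moved by 0.5 on the log2 scale, 65.67% of those moved by 1 and 100% of those moved by 2 in a single-treatment contrast. For the interaction term the same shares were 1.493%, 38.81% and 89.39%. Over both steps, 5 genes that were not moved were called in each.

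The alternatives tried were the mean of a gene's probe sets, every probe set on its own, no filter and a filter at the 60th percentile (a log2 level of 5.70), median centring, cyclic loess, eBayes with trend and robust estimation, array weights, no replicate block (cell line left out of the model), cell line as a random block, a fit of only the 2 groups compared, a threshold of at least 2-fold, an estimated inter-gene correlation for the lists, and each cell line left out of all groups in turn. Added after seeing the data were a fit without the OCI-LY10 IRAKi array and scaling of each array to its poly-A spike-in probe sets. Control probe sets and probe sets with several genes or none were left out of the comparisons and are described separately.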

Results

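RNA levels were measured on 12 expression arrays, 1 for each of 3 cell lines under each of 4 treatments. OCI-LY3 (replicate 1), OCI-HBL1 (replicate 2) and OCI-LY10 (replicate 3) are established human lines of ABC-DLBCL, a lymphoma with chronic NF-kB signalling. Each line had a Control array, whose treatment label says no more, and 3 arrays of treated cells. CPI203, an inhibitor of the BET bromodomain proteins that read acetylated chromatin, was given at 500 nM. An inhibitor of the kinases that signal below MYD88 (IRAKi, its chemical identity not stated) was given at 50 µM. Combo cells were given both, so that n = 3 in each group. The labels give 24 h for Control, CPI203 and Combo and 6 h for IRAKi, while the protocol gives 18 h of the BET inhibitor and 6 h of the IRAK inhibitor. Treatment and label time therefore differ together in every comparison of IRAKi alone with another group. Because the replicates are cell lines, the p-values measure only the spread between these samples.

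Array medians ranged from 4.64 to 4.74 on the log2 scale, and the correlation between 2 arrays from 0.923 to 0.991. The first components of the variation, with 40.7% and 34.4%, parted the cell lines, and the next, with 13.1%, parted the treatments. The OCI-LY10 IRAKi array had non-specific control probe sets at a log2 level of 4.00, against 3.64 to 3.79 on the other arrays. Relative to Control, the poly-A RNA spiked into each sample read higher by 0.31 ± 0.17 with CPI203, 0.23 ± 0.04 with IRAKi and 0.48 ± 0.26 with Combo (log2, SD, n = 3). Levels below are those of the deposited scale, on which the median gene moves by between -0.0104 and 0.00811 in the 5 comparisons.

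CPI203 alone, at the same label time as Control, shows the response to BET inhibition. HEXIM1, whose product holds the elongation kinase P-TEFb inactive and whose RNA is a common marker of BET inhibition, rose by 1.81 ± 0.20 (log2 change ± SE, n = 3, adjusted p = 0.0014). LMO2, a transcriptional adaptor of germinal centre B cells, rose by 2.65 ± 0.37 (adjusted p = 0.0035), and the histone gene H2BC5 by 2.57 ± 0.18 (adjusted p = 0.00022). The mean of LMO2 in Control was below the filter level of 4.20, so its rise may be larger. TNFRSF17, the plasma cell receptor BCMA, changed by -3.53 ± 0.29 (adjusted p = 0.00053), and the B cell surface protein CD72 changed by -2.40 ± 0.32 (adjusted p = 0.0027). With CPI203, TNFRSF17 was below the filter level of 4.20 in OCI-LY3 and OCI-LY10, so its fall there may be larger. MYC had a log2 change of -0.57 ± 0.21 and did not pass the test (adjusted p = 0.11).

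Among the lists, the histone genes rose with CPI203 (median log2 change 1.00, adjusted p = 6.1e-08). Of 19 measured members 8 rose, none fell and 11 did not pass, and 12 rose when adjusted over the list alone, with H2AC6 at 2.66 ± 0.31, H2BC21 at 2.47 ± 0.47 and H1-2 at 1.61 ± 0.20. The adjusted p was 0.111 with an estimated correlation. The BET proteins and BET inhibitor response genes rose as well (median 0.79, adjusted p = 6.3e-05, and adjusted p = 0.097 with an estimated correlation). Of 10 members 6 rose, none fell and 4 did not pass, and adjusted over the list alone 7 rose and 1 fell. BRD2, itself a BET protein, rose by 0.74 ± 0.10, while BRD3 had a change of 0.34 ± 0.11 that did not pass (adjusted p = 0.076). Immediate early genes were called higher (median 0.22, adjusted p = 0.042, and adjusted p = 0.552 with an estimated correlation), with 1 of 19 members called, also when adjusted over the list alone, the zinc finger factor EGR1 at 1.30 ± 0.28. This call was lost without OCI-HBL1 (adjusted p = 0.12) and without OCI-LY10 (adjusted p = 0.0505). Scaled to the poly-A spike-ins, which shifts the median gene down, the list's median turned negative, while camera still called it higher.

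The interferon response list fell furthest with CPI203 (median -0.82, adjusted p = 6.1e-08, and adjusted p = 0.111 with an estimated correlation). Of 28 members none rose, 11 fell and 17 did not pass, and 17 fell when adjusted over the list alone. Examples are the antiviral genes SAMD9L at -1.64 ± 0.19, OAS1 at -1.21 ± 0.23 and MX2 at -1.08 ± 0.21. B cell identity genes fell (median -0.28, adjusted p = 6.3e-05, and adjusted p = 0.111 with an estimated correlation), with 9 of 29 members fallen and none risen, also when adjusted over the list alone. They include the kinase gene BLK at -1.44 ± 0.16 and MS4A1, which encodes CD20, at -0.75 ± 0.12. The ABC-DLBCL signature fell (median -0.39, adjusted p = 7e-05, and adjusted p = 0.156 with an estimated correlation), with 5 of 23 members fallen, or 9 fallen and 1 risen adjusted over the list alone. ENTPD1, which encodes the ectonucleotidase CD39, fell by 1.42 on the log2 scale (SE 0.15), and the cytokine gene IL16 by 1.88 (SE 0.34). The plasma cell and secretory programme was called lower (median -0.30, adjusted p = 0.014, and adjusted p = 0.552 with an estimated correlation), with 5 of 18 members fallen, or 6 adjusted over the list alone, among them FKBP11, a protein-folding gene of the secretory pathway, at -0.72 ± 0.14. This call was lost without OCI-LY10 (adjusted p = 0.0669).

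MYC targets and ribosome biogenesis genes fell with CPI203 (median -0.21, adjusted p = 5.7e-05, and adjusted p = 0.311 with an estimated correlation). Of 34 members 9 fell and none rose, or 14 fell and 1 rose adjusted over the list alone, including the folate carrier gene SLC19A1 at -1.34 ± 0.19 and TCOF1, a factor of ribosomal RNA transcription, at -0.75 ± 0.12. DNA replication genes fell (median -0.29, adjusted p = 0.0018, and adjusted p = 0.405 with an estimated correlation), with 5 of 30 members fallen, or 9 adjusted over the list alone, among them the helicase gene MCM2 at -0.90 ± 0.14 and the polymerase gene POLE2 at -0.91 ± 0.17. JAK-STAT3 targets were called lower (median -0.17, adjusted p = 0.042, and adjusted p = 0.552 with an estimated correlation), with 2 of 20 members fallen, also when adjusted over the list alone, BATF at -1.41 ± 0.28 and IL21R at -1.02 ± 0.19. This call was lost without OCI-LY3 (adjusted p = 0.146) and without OCI-LY10 (adjusted p = 0.0669). NF-kB targets were not called (median -0.10, adjusted p = 0.46), with 3 of 37 members risen and 6 fallen. The pathway genes MYD88 and IRAK1 fell by 0.72 (SE 0.13) and 0.61 (SE 0.17) on the log2 scale.

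In all, limma called 1723 of 13120 genes for CPI203 against Control, 908 risen and 815 fallen, and each moved one way in all 3 lines. The count was 216 without OCI-LY3, 720 without OCI-HBL1 and 282 without OCI-LY10, and 4 with the cell line left out of the model. Scaled to the poly-A spike-ins, which shifts the median gene by -0.298, 165 genes rose and 1595 fell.

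IRAKi alone was compared with Control, with label times of 6 h and 24 h. KLHL14, a kelch-family gene, fell by 1.90 on the log2 scale (SE 0.27, n = 3, adjusted p = 0.038). CD24, a B cell surface glycoprotein, fell by 1.55 (SE 0.21, adjusted p = 0.035), ENTPD1 by 1.22 (SE 0.15, adjusted p = 0.029), the pro-apoptotic BH3-only gene BMF by 1.12 (SE 0.15, adjusted p = 0.029) and the adaptor gene HSH2D by 1.00 (SE 0.15, adjusted p = 0.04). The non-coding RNA LINC00158 fell by 1.42 (SE 0.15, adjusted p = 0.017) and CLECL1 by 0.74 (SE 0.11, adjusted p = 0.039). C1S, a complement protease gene, rose by 1.56 ± 0.15 (adjusted p = 0.013), DNHD1, a dynein-related gene, by 1.76 ± 0.16 (adjusted p = 0.013) and MCF2, a guanine nucleotide exchange factor gene, by 1.28 ± 0.19 (adjusted p = 0.048). MYC had a change of -0.35 ± 0.21 and did not pass (adjusted p = 0.47).

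Genes of ATF4 and the integrated stress response were called higher with IRAKi as a list (median 0.31, adjusted p = 0.0003, and adjusted p = 0.247 with an estimated correlation). None of the 24 members passed over all genes, and 7 rose adjusted over the list alone. The stress gene SESN2 stood at 0.89 ± 0.18, the cystine transporter gene SLC7A11 at 1.13 ± 0.26 and asparagine synthetase, ASNS, at 0.44 ± 0.10. The heat shock response was called lower (median -0.27, adjusted p = 9.4e-05, and adjusted p = 0.247 with an estimated correlation). None of its 18 members passed over all genes and 2 fell adjusted over the list alone, with the chaperone genes HSPA1B at -1.24 ± 0.32 and DNAJA1 at -0.59 ± 0.13. Non-specific control probe sets were 0.29 higher on the OCI-LY10 IRAKi array than on that line's Control array.

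MYC targets and ribosome biogenesis genes were called lower with IRAKi (median -0.17, adjusted p = 9.4e-05, and adjusted p = 0.247 with an estimated correlation), with none of 34 members past the test on either adjustment, over all genes or adjusted over the list alone. SLC19A1 stood at -0.69 ± 0.19 and TCOF1 at -0.47 ± 0.12. The interferon response was called lower (median -0.35, adjusted p = 0.00038, and adjusted p = 0.247 with an estimated correlation), with none of 28 members passing and 1 fallen adjusted over the list alone, and IFI35 at -0.73 ± 0.16. DNA replication genes were called lower (median -0.14, adjusted p = 0.00052, and adjusted p = 0.247 with an estimated correlation), with none of 30 members passing, nor any adjusted over the list alone, and MCM4 at -0.32 ± 0.11.

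B cell identity genes (median -0.26, adjusted p = 0.0064, and adjusted p = 0.247 with an estimated correlation) and the ABC-DLBCL signature (median -0.16, with the same p-values) were called lower with IRAKi. In each list 1 member fell, CD24 of 29 and ENTPD1 of 23, and adjusted over the list alone 1 B cell identity gene rose and 1 fell, and 3 signature genes fell. Cholesterol synthesis and uptake genes were called lower (median -0.15, adjusted p = 0.021, and adjusted p = 0.247 with an estimated correlation), with none of 19 members past the test on either adjustment, over all genes or adjusted over the list alone, and HMGCS1, an enzyme of the mevalonate pathway, at -0.73 ± 0.20. The plasma cell and secretory programme was called lower (median -0.06, adjusted p = 0.046, and adjusted p = 0.581 with an estimated correlation), with none of 18 members past the test and 2 fallen adjusted over the list alone, and MZB1 at -0.62 ± 0.14. The cholesterol call was lost without OCI-LY3 (adjusted p = 0.253), and the plasma cell call without OCI-LY3 (adjusted p = 0.253), without OCI-LY10 (adjusted p = 0.28) and without the OCI-LY10 IRAKi array alone (adjusted p = 0.092). NF-kB targets were not called with IRAKi (median -0.07, adjusted p = 0.55), and none of 37 members passed the test.

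For IRAKi against Control limma called 22 genes, 15 risen and 7 fallen, while 2018 had an unadjusted p below 0.05, against 656 that chance gives. None was called without OCI-LY3, without OCI-HBL1 or without OCI-LY10, nor without the OCI-LY10 IRAKi array, where limma gave 1349, 1791, 1227 and 1601 genes with an unadjusted p below 0.05. With trend and robust estimation limma called 220, which include the 22. The mean of a gene's probe sets gave 13 genes, of which only 7 were among the 22, and a fit of only the 2 groups gave 0. Scaled to the poly-A spike-ins, which shifts the median gene by -0.23, 2 genes rose and 24 fell, and only 8 of the 22 stayed called.

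**Figure D1:**
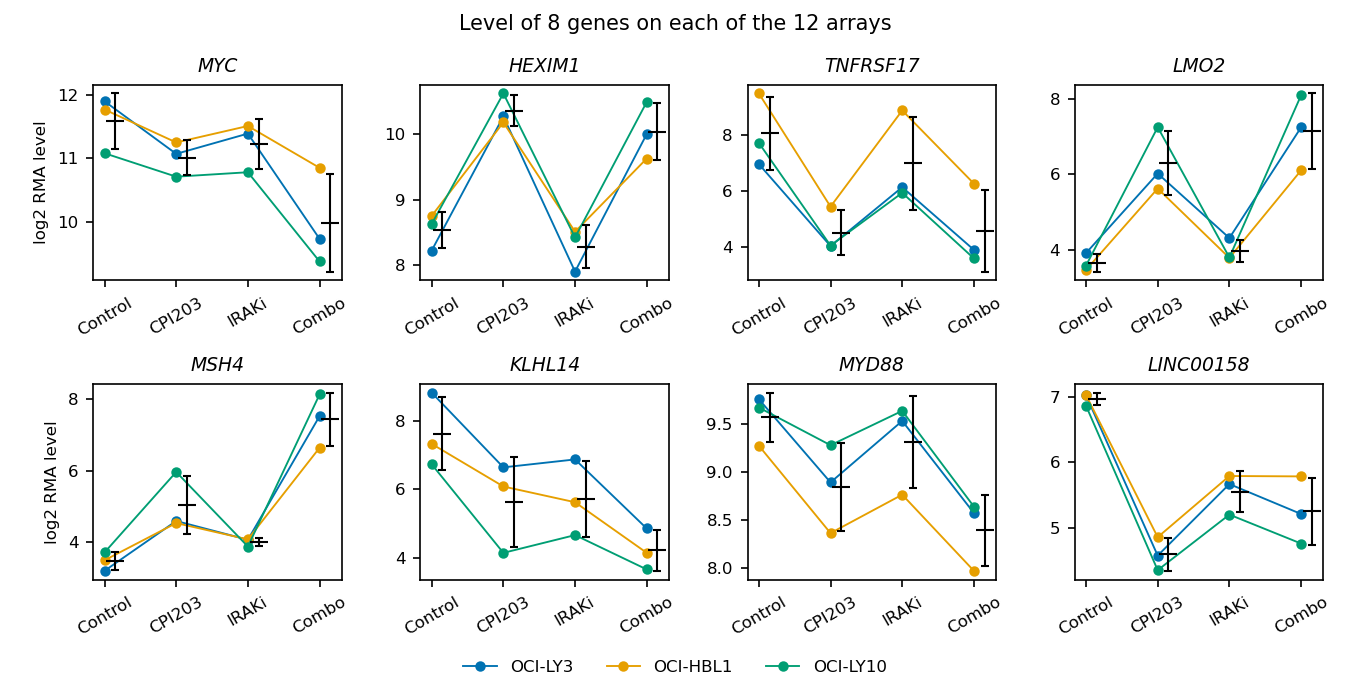
Log2 RMA level (vertical axis) of 8 genes in the 4 treatment groups, with 1 point per array, lines joining the arrays of a cell line, and black marks for the group mean ± SD (n = 3). HEXIM1 is higher in CPI203 and Combo than in Control in all 3 lines, and MYC is lowest in Combo in all 3 lines.

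Combo against Control gives the joint response to both inhibitors. MYC, the growth-promoting transcription factor, fell by 1.60 on the log2 scale (SE 0.21, n = 3, adjusted p = 0.00059), with changes of -2.17 in OCI-LY3, -0.92 in OCI-HBL1 and -1.71 in OCI-LY10. MYD88, the adaptor above the IRAK kinases, fell by 1.18 (SE 0.13, adjusted p = 0.00024) and IRAK1 by 0.65 (SE 0.17, adjusted p = 0.015). ARID5B, a chromatin regulator gene, changed by -3.51 ± 0.17 (adjusted p = 2.2e-05), TNFRSF17 by -3.45 ± 0.29, KLHL14 by -3.40 ± 0.27 and the phosphodiesterase gene PDE4B by -3.09 ± 0.54. With Combo, TNFRSF17 in OCI-LY3 and OCI-LY10 and KLHL14 in OCI-HBL1 and OCI-LY10 were below the filter level of 4.20. The falls of TNFRSF17 and KLHL14 in these lines may therefore be larger. DHRS2, a dehydrogenase/reductase gene, rose by 3.99 ± 0.67, MSH4, a meiotic gene of the mismatch repair family, by 3.96 ± 0.32 and LMO2 by 3.50 ± 0.37. The means of these 3 genes in Control were below the filter level of 4.20, so their rises may be larger. FOS, a component of the AP-1 transcription factor, rose by 3.11 ± 0.71 (adjusted p = 0.0086), with changes of 0.17, 4.21 and 4.96 in OCI-LY3, OCI-HBL1 and OCI-LY10.

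Histone genes rose with Combo (median 1.74, adjusted p = 7e-08, and adjusted p = 0.139 with an estimated correlation). Of 19 members 15 rose, none fell and 4 did not pass, and 16 rose adjusted over the list alone, with H2AC6 at 3.66 ± 0.31 and H2BC21 at 3.05 ± 0.47. BET proteins and BET inhibitor response genes rose (median 1.25, adjusted p = 0.00027, and adjusted p = 0.139 with an estimated correlation), with 7 of 10 risen and MYC fallen, or 9 risen and 1 fallen adjusted over the list alone. HEXIM1 rose 2.82-fold (adjusted p = 0.00058) and BRD2 by 1.01 ± 0.10 on the log2 scale. Immediate early genes rose (median 0.48, adjusted p = 0.0012, and adjusted p = 0.412 with an estimated correlation), with 7 of 19 risen and none fallen, also when adjusted over the list alone, and EGR1 at 1.91 ± 0.28 and NR4A3 at 1.76 ± 0.36. Poly-A spike-ins rose beside them by 0.48, and scaled to these the immediate early list's median was -0.00729.

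The ABC-DLBCL signature fell with Combo (median -0.76, adjusted p = 2.6e-06, and adjusted p = 0.139 with an estimated correlation). Of 23 members 13 fell, none rose and 10 did not pass, and 16 fell adjusted over the list alone, with IL16 at -2.68 ± 0.34, the transcription factor gene BATF at -2.13 ± 0.28 and the potassium channel gene KCNA3 at -1.83 ± 0.18. MYC targets and ribosome biogenesis genes fell (median -0.40, adjusted p = 8.8e-07, and adjusted p = 0.207 with an estimated correlation), with 17 of 34 fallen and 1 risen, also when adjusted over the list alone. The ribosome assembly genes RRS1, WDR12 and NOP16 stood at -1.37 ± 0.11, -1.17 ± 0.13 and -1.14 ± 0.11, and ODC1, an enzyme of polyamine synthesis, rose by 0.29 ± 0.10 but stood at -0.19 when arrays were scaled to the poly-A spike-ins.

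B cell identity genes fell with Combo (median -0.60, adjusted p = 0.00089, and adjusted p = 0.169 with an estimated correlation), with 14 of 29 fallen and none risen, or 15 fallen adjusted over the list alone. BLK fell by 1.62 (SE 0.16), the B cell transcription factor gene EBF1 by 1.35 (SE 0.19) and the kinase gene SYK by 1.08 (SE 0.15). The interferon response fell (median -0.62, adjusted p = 8.4e-05, and adjusted p = 0.223 with an estimated correlation), with 12 of 28 fallen and 2 risen, or 14 and 2 adjusted over the list alone. PARP9 stood at -2.28 ± 0.20 and SAMD9L at -2.18 ± 0.19, while IFIT2 and IRF7 rose by 0.93 ± 0.31 and 0.81 ± 0.27. The mean of IFIT2 in Control was below the filter level of 4.20, so its rise may be larger. DNA replication genes fell (median -0.23, adjusted p = 0.0033, and adjusted p = 0.412 with an estimated correlation), with 12 of 30 fallen and 1 risen, or 14 and 1 adjusted over the list alone. POLE2 stood at -1.50 ± 0.17, and the histone mRNA binding gene SLBP rose by 0.34 ± 0.11 but stood at -0.14 when scaled to the spike-ins.

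**Figure D2:**
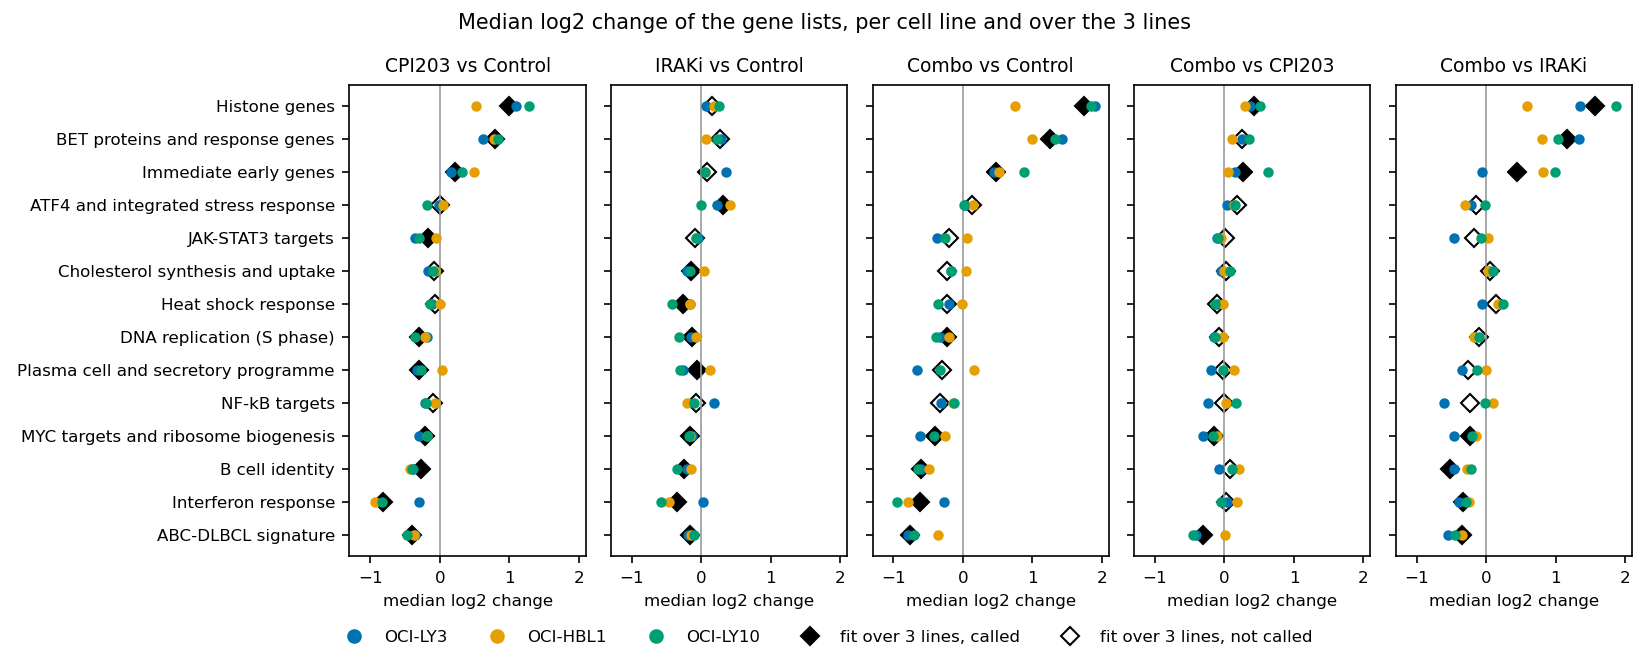
Median log2 change (horizontal axis) of the gene lists called in at least 1 comparison, and of NF-kB targets, in the 5 comparisons, with coloured points for each cell line and diamonds for the fit over 3 lines, filled where camera called the list. Histone genes have the highest median in Combo against Control, 1.74, and the ABC-DLBCL signature the lowest, -0.76; scaled to the poly-A spike-ins the immediate early list's median turns to -0.0876 with CPI203 and -0.00729 with Combo.

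NF-kB targets, the pathway that the study's title names, moved in both directions with Combo and were not called as a list (median -0.33, adjusted p = 0.387, and adjusted p = 0.737 with an estimated correlation). The median was -0.13 without OCI-LY3, -0.24 without OCI-HBL1 and -0.22 without OCI-LY10, and the list stayed uncalled. Of 37 measured members 10 fell, 8 rose and 19 did not pass, also when adjusted over the list alone. Genes to fall were TRAF1, a signalling adaptor, at -2.25 ± 0.37, BATF at -2.13 ± 0.28, the adhesion gene ICAM1 at -1.86 ± 0.24, BCL3 at -1.84 ± 0.47, CD80 at -1.50 ± 0.20 and the caspase inhibitor CFLAR at -1.27 ± 0.21. Genes to rise were the chemokine CCL3 at 2.26 ± 0.63, IER3 at 1.44 ± 0.12, GADD45B at 1.44 ± 0.15, REL, an NF-kB subunit, at 0.87 ± 0.24, and NFKBIA, which encodes the inhibitor IkB-alpha, at 0.83 ± 0.21. BATF, CCL3, REL and NFKBIA came from the rule for named genes, and the other 7 were chosen after their values were seen. The subunit genes NFKB1, NFKB2 and RELB, the feedback gene TNFAIP3, the cytokine genes IL6 and IL10, and IRF4 did not pass. NF-kB targets were likewise not called in Combo against CPI203 (median -0.01, adjusted p = 0.969) or Combo against IRAKi (median -0.23, adjusted p = 0.504), whose medians without OCI-LY3 were 0.0457 and 0.0693. Without OCI-LY3 the list was called lower with IRAKi against Control (median -0.16, adjusted p = 0.0243).

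**Figure D3:**
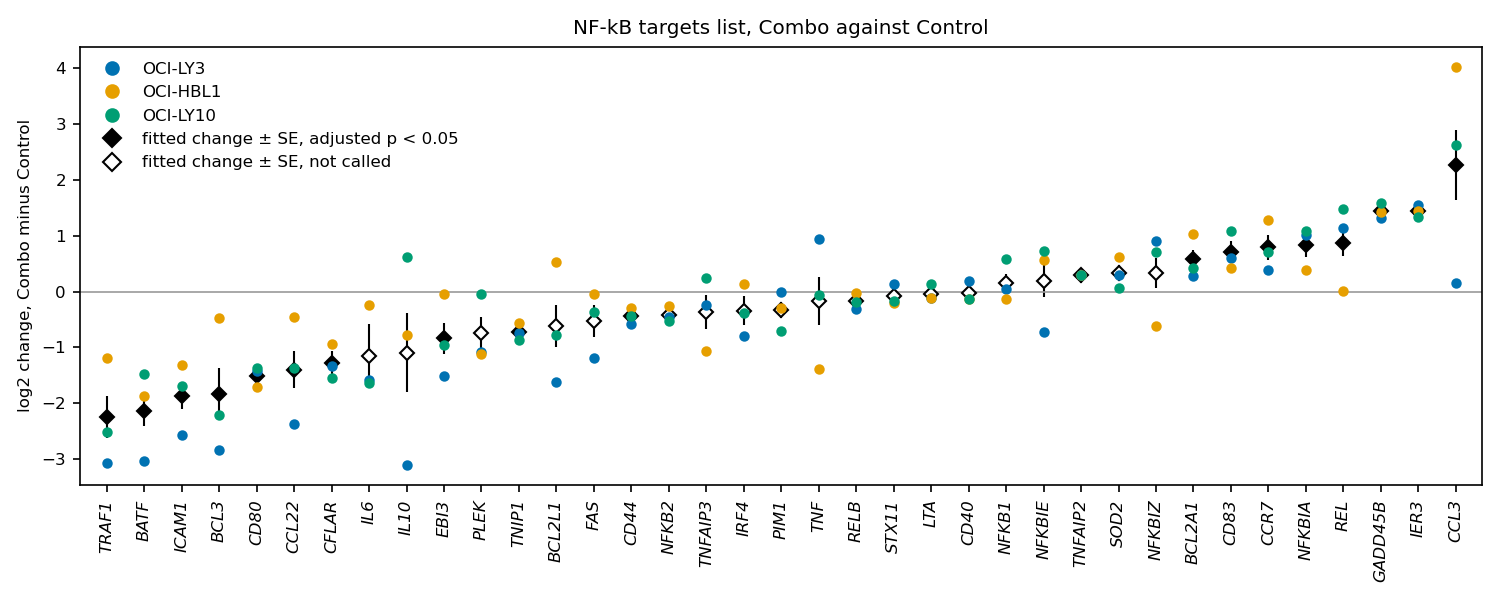
Log2 change of the 37 measured NF-kB targets in Combo against Control (vertical axis), sorted by size, with coloured points for each cell line and diamonds for the fitted change ± SE (n = 3), filled at an adjusted p below 0.05. The members range from TRAF1 at -2.25 to CCL3 at 2.26, with 10 called lower and 8 called higher.

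Of the apoptosis and cell cycle genes fixed in advance, BCL2A1 and MCL1, relatives of BCL2 that oppose apoptosis, rose with Combo by 0.58 ± 0.17 (adjusted p = 0.026) and 0.60 ± 0.15 (adjusted p = 0.013), and the cyclin kinase inhibitor gene CDKN1A by 0.76 ± 0.21 (adjusted p = 0.023). BCL2, BCL2L1, BCL6, PIM1, CXCR4 and CD69 did not pass. Over all genes limma called 4214 for Combo against Control, 2023 risen and 2191 fallen, of which 4151 moved one way in all 3 lines. The count was 2072 without OCI-LY3, 3420 without OCI-HBL1 and 2232 without OCI-LY10, and 465 with the cell line left out of the model. Median centring gave 2465 risen and 1784 fallen, and scaling to the poly-A spike-ins, which shifts the median gene by -0.487, gave 513 and 5644.

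Combo against CPI203, at 1 label time, asks what the IRAK inhibitor adds to the BET inhibitor. MYC fell by a further 1.03 on the log2 scale (SE 0.21, n = 3, adjusted p = 0.031), with changes of -1.34 in OCI-LY3, -0.40 in OCI-HBL1 and -1.34 in OCI-LY10. BCL11A, a transcription factor gene of B lymphoid cells, changed by -1.70 ± 0.23 (adjusted p = 0.0095), BMF by -1.48 ± 0.15 (adjusted p = 0.005), KLHL14 by -1.40 ± 0.27 and UCK2, an enzyme of pyrimidine salvage, by -1.49 ± 0.24. TNFSF13B, which encodes the B cell survival factor BAFF, rose by 2.33 ± 0.31 (adjusted p = 0.0095), MSH4 by 2.40 ± 0.32 and the interleukin receptor gene IL1R1 by 1.93 ± 0.45.

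MYC targets and ribosome biogenesis genes were lower with Combo than with CPI203 (median -0.15, adjusted p = 5.8e-05, and adjusted p = 0.662 with an estimated correlation), with 7 of 34 fallen and none risen, or 12 fallen adjusted over the list alone. RRS1 stood at -0.86 ± 0.11, WDR12 at -0.79 ± 0.13 and POLR1B, a subunit of RNA polymerase I, at -0.80 ± 0.16. The ABC-DLBCL signature was lower (median -0.31, adjusted p = 0.00077, and adjusted p = 0.662 with an estimated correlation), with 2 of 23 fallen, KCNA3 at -1.31 ± 0.18 and TCF4 at -0.82 ± 0.17, or 5 fallen adjusted over the list alone. Histone genes were called higher (median 0.43, adjusted p = 0.0011, and adjusted p = 0.662 with an estimated correlation), with none of 19 members past the test on either adjustment, over all genes or adjusted over the list alone, H2AC6 at 1.00 ± 0.31 and H3C4 at 1.04 ± 0.34. Immediate early genes were called higher (median 0.27, adjusted p = 0.01, and adjusted p = 0.697 with an estimated correlation), with 1 of 19 risen, also when adjusted over the list alone, NR4A3 at 1.58 ± 0.36, and the list's call was lost without OCI-LY10 (adjusted p = 0.208).

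For Combo against CPI203 limma called 612 genes, 257 risen and 355 fallen. It called none without OCI-LY3, 3 without OCI-HBL1 and none without OCI-LY10, where 1805 and 1853 genes had an unadjusted p below 0.05 in the first and last of these fits. A fit of only the 2 groups called 198, one without the cell line 2, and one with trend and robust estimation 954. Median centring gave 406 risen and 240 fallen, cyclic loess 302 and 261, and scaling to the poly-A spike-ins, which shifts the median gene by -0.188, 79 and 336.

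Combo against IRAKi asks what the BET inhibitor adds to the IRAK inhibitor, with label times of 24 h and 6 h. ARID5B changed by -2.71 ± 0.17, TNFRSF17 by -2.39 ± 0.29 and TRAF5, a signalling adaptor gene, by -2.04 ± 0.15 (log2 change ± SE, n = 3). TNFRSF17 was below the filter level of 4.20 with Combo in OCI-LY3 and OCI-LY10, so its fall there may be larger. MYC fell by 1.25 (SE 0.21, adjusted p = 0.0045) and MYD88 by 0.92 (SE 0.13, adjusted p = 0.0019). MSH4 and LMO2 rose by 3.42 ± 0.32 and 3.19 ± 0.37. Their means in IRAKi were below the filter level of 4.20, so these rises may be larger. SERPINE2, a serine protease inhibitor gene, rose by 2.29 ± 0.15, HEXIM1 by 1.75 ± 0.20 and the cyclin kinase inhibitor gene CDKN1A 2.14-fold.

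Histone genes rose in this comparison (median 1.57, adjusted p = 2.1e-09, and adjusted p = 0.143 with an estimated correlation), with 14 of 19 risen and none fallen, also when adjusted over the list alone, and H2AC6 at 2.96 ± 0.31. BET proteins and BET inhibitor response genes rose (median 1.16, adjusted p = 0.00063, and adjusted p = 0.143 with an estimated correlation), with 6 of 10 risen and 1 fallen, or 7 and 1 adjusted over the list alone. Immediate early genes rose (median 0.44, adjusted p = 0.0012, and adjusted p = 0.482 with an estimated correlation), with 5 of 19 risen, or 6 adjusted over the list alone, and FOS at 3.07 ± 0.71. The ABC-DLBCL signature fell (median -0.35, adjusted p = 1.1e-05, and adjusted p = 0.155 with an estimated correlation), with 9 of 23 fallen, or 11 adjusted over the list alone. MYC targets and ribosome biogenesis genes fell (median -0.22, adjusted p = 2.1e-05, and adjusted p = 0.324 with an estimated correlation), with 14 of 34 fallen, or 15 fallen and 1 risen adjusted over the list alone. B cell identity genes fell (median -0.52, adjusted p = 0.01, and adjusted p = 0.324 with an estimated correlation), with 8 of 29 fallen, or 10 fallen and 1 risen adjusted over the list alone. The interferon response fell (median -0.33, adjusted p = 0.011, and adjusted p = 0.512 with an estimated correlation), with 7 of 28 fallen and 1 risen, also when adjusted over the list alone, PARP9 at -1.95 ± 0.20 and IRF7 at 1.16 ± 0.27.

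For Combo against IRAKi limma called 2456 genes, 1077 risen and 1379 fallen. The count was 526 without OCI-LY3, 1704 without OCI-HBL1, 730 without OCI-LY10, 1487 without the OCI-LY10 IRAKi array alone, 977 in a fit of only the 2 groups and 7 without the cell line in the model. Median centring gave 1691 risen and 994 fallen, and scaling to the poly-A spike-ins, which shifts the median gene by -0.255, gave 350 and 1940.

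Of the 26 lists, 12 besides NF-kB targets were not called in any of the 5 comparisons. Antigen presentation genes came closest, with a lowest adjusted p of 0.0526 and 6 of 23 members fallen in Combo against Control. The lowest adjusted p was 0.055 for NRF2 targets, 0.156 for hypoxia and glycolysis, 0.162 for unfolded protein response chaperones, 0.265 for AHR targets, 0.291 for the germinal centre signature and 0.304 for p53 targets. It was 0.435 for apoptosis regulators and 0.757 for mitosis genes. T cell and NK cell markers, of which 10 of 14 were bright enough to test, had a lowest adjusted p of 0.686, and monocyte and macrophage markers, with 4 of 14 tested, 0.439, with no member of either called in Combo against Control.

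The study's title speaks of synergy and of convergence. The interaction term asks only whether log2 RNA changes add up, and the correlations only whether effects on RNA are alike. The arrays measure RNA, so a synergy in cell growth or survival is outside these values. LINC00158 was the 1 gene called for a departure from additive log2 changes, at 2.07 ± 0.21 (n = 3, adjusted p = 0.037). The term includes the difference in label time between IRAKi and Control. LINC00158 fell by 2.37 with CPI203 and by 1.42 with IRAKi, and was higher in Combo than in CPI203 by 0.66 (adjusted p = 0.043). With CPI203 its level was 4.577 in OCI-LY3, 4.858 in OCI-HBL1 and 4.355 in OCI-LY10. A further fall of 1.42 would take it below the filter level of 4.20, where falls may be understated. Part of the 2.07 may therefore come from this lower limit, while the rise of 0.66 over CPI203 lies above it. No other gene departed detectably, while 1085 had an unadjusted p below 0.05 in limma, and the median 95% interval reached 0.495 on either side of a gene's estimate. LINC00158 was not called without OCI-LY3, OCI-HBL1 or OCI-LY10, nor without the OCI-LY10 IRAKi array, where 763, 907, 817 and 1051 genes had an unadjusted p below 0.05. Over the 4214 genes called for Combo against Control, the change with Combo had a slope of 0.964 on the sum of the single effects (r = 0.93, across genes), where both sides use the same Control arrays and the genes were selected on 1 of the sides.

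**Figure D4:**
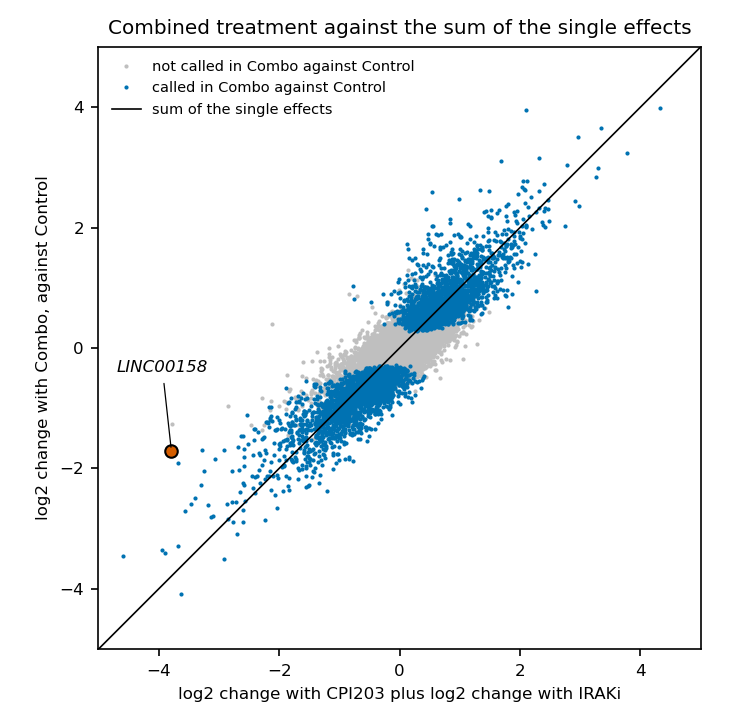
Log2 change with Combo against Control (vertical axis) plotted on the sum of the log2 changes with CPI203 and IRAKi (horizontal axis), 1 point per gene for 13120 genes, blue where called for Combo, with a line where both are equal. The called genes have a slope of 0.964 on the sum, and LINC00158, marked in orange, lies 2.07 above the line.

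The effects of CPI203 and IRAKi correlated across genes with r = 0.581 and rho = 0.534. In 100 simulations of unchanged groups sharing the Control arrays, r was 0.501, from 0.469 to 0.526. Those groups hold no treatment effect, so the gap between the r values does not give the size of a common effect. The covariance of the effects was 0.0702, against a mean of 0.0175 in the simulations. Between different lines, which share no Control array, the 6 pairs gave r from 0.237 to 0.317. Of the genes called for IRAKi, 12 of 15 risen and 5 of 7 fallen were called in the same direction for CPI203. Both comparisons use the same Control arrays, so no expectation is given. In arrays that share no sample, the CPI203 effect without IRAKi correlated with that in its presence at r = 0.753 (rho = 0.681), and the IRAKi effect without CPI203 with that in its presence at r = 0.48 (rho = 0.429). Of the 22 genes called for IRAKi against Control, 10 that rose and 5 that fell were called the same way in Combo against CPI203. Independence gives 0.294 and 0.189, and LINC00158 was called in the opposite direction. Both comparisons take each gene's spread from the same fit, so calls can coincide more often than independence gives without a common effect.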

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

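The tests of sampling time, of the spike-in and ribosomal RNA probe sets, of relabelled gene lists for the interaction term, of NF-kB targets with IRAKi in single lines, and of whether the bright NF-kB targets alone were called lower were chosen only after the results they address were seen.

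The genes called for IRAKi against Control come from arrays with label times of 6 h and 24 h. If the time alone accounted for them, they would show no common shift in Combo against CPI203, where the label time is the same and no array is shared. There the 22 genes moved by a median of 0.689 in the direction of their call (quartiles 0.327 and 1.17). Of them, 20 moved the same way and 15 were called. This argues against time as the whole cause for the genes only if Combo and CPI203 were sampled at the same time, as labelled. The protocol gives 18 h of the BET inhibitor and 6 h of the IRAK inhibitor, so the sampling times of Combo and CPI203 may have differed. The lists stay open, since 2 of the 9 called with IRAKi were also called in Combo against CPI203 and 6 had a median of the same sign. If the labels hold, an effect of the IRAK inhibitor may underlie the called genes. For the lists, time and treatment cannot be told apart, because they differ together in the labels.

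NF-kB targets were not called lower in any comparison over all 3 lines, although the study's title names NF-kB blockade. A fall hidden by a single line is argued against in Combo against Control, where only 1 line, OCI-LY3, had a median below -0.2 (-0.31, with -0.143 in OCI-HBL1 and -0.128 in OCI-LY10), but with IRAKi a single line may hide one, since the median was 0.18 in OCI-LY3, -0.206 in OCI-HBL1 and -0.111 in OCI-LY10, and without OCI-LY3 the list was called lower (-0.157, adjusted p = 0.0243), in 1 of 15 fits that leave out a line. Members too dim to fall could be only a few in Combo against Control, as 33 of 37 were bright. The bright members alone were not called lower (median -0.333, adjusted p = 0.418), but they are most of the list, so this largely repeats its result. Their median lies below the level set beforehand for this cause, as does that of the whole list, so the test does not decide. Members that moved in opposite directions are in line with the data for Combo against Control, since 48.6% of members were called against 32.1% of all genes, 10 fallen and 8 risen.

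Poly-A spike-in probe sets, data outside the comparisons, read higher than in Control by 0.306 with CPI203, 0.229 with IRAKi and 0.484 with Combo, and ribosomal RNA probe sets by 0.243, 0.249 and 0.511 (log2, means of 3 lines). Hybridisation and scanning are argued against as the whole cause with Combo, since there the spike-ins rose by 0.33 more than the hybridisation controls (0.203 to 0.523 over the lines, SD 0.17). With CPI203 and IRAKi the causes cannot be told apart, because the excess, 0.131 and 0.2 on average, ranged over the lines from -0.00188 to 0.332 and from 0.0366 to 0.341. Less messenger RNA per total RNA is in line with the ribosomal RNA rise of 0.511 with Combo (0.356 to 0.631, SD 0.141), while unequal addition of the spike-ins was not tested on its own. Scaled to the spike-ins, limma called fewer genes risen in each of the 5 comparisons and more fallen in 4, while in Combo against CPI203 it called 336 fallen, against 355 on the deposited scale.

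LINC00158 had an interaction term of 2.07, a difference between the IRAKi effects with and without CPI203, which mixes interaction with label time, since IRAKi against Control compares 6 h with 24 h and Combo against CPI203 equal label times. Part of the 2.07 may also come from the lower limit of the arrays, since additive falls would take LINC00158 below the filter level of 4.20. LINC00158 is 1 of the 2 genes, among the 22 called for IRAKi, that went the other way in Combo against CPI203. It was not called without any 1 of the 3 lines or without the OCI-LY10 IRAKi array. Relabelling the treatments within the lines called as many genes in 3 of 100 cases, the real one included, and the highest other called 3349. Such relabellings turn a treatment effect into the term, so the count decides nothing about chance. The interferon response list (median 0.306, adjusted p = 0.014) and the heat shock list (median 0.159, adjusted p = 0.014) were called for the interaction term, but each had an adjusted p of 0.817 with an estimated correlation. Relabelling decides nothing for the lists either, where 81 of 100 cases called as many, up to 13.

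Some list medians in 1 line lay on the other side of 0 from the other 2 lines, a difference that was not tested, as each line has 1 array per treatment. In OCI-HBL1 the plasma cell and secretory programme stood at 0.0349 with CPI203 and 0.123 with IRAKi, cholesterol genes at 0.0421 with IRAKi, and the ABC-DLBCL signature at 0.00037 in Combo against CPI203. In OCI-LY3 the interferon response stood at 0.027 with IRAKi, and immediate early genes at -0.0576 in Combo against IRAKi. In OCI-LY10 the ATF4 list stood at -0.00241 with IRAKi.

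Of 4040 probe sets with several genes or none, controls aside, which the comparisons leave out, 2494 passed the filter. Of these limma called 179 for CPI203, 633 for Combo, 62 for Combo against CPI203 and 269 for Combo against IRAKi. It called 0 for IRAKi against Control, where 353 had an unadjusted p below 0.05.

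Other splits of the 6 arrays of a comparison number 10 with the real one, too few for a share below 0.1. In genes called, 1 split, the real one, reached the count in each comparison, with 1723 genes for CPI203, 22 for IRAKi, 4214 for Combo, 612 for Combo against CPI203 and 2456 for Combo against IRAKi. The highest other split called 1 gene for Combo against Control and 0 in the other 4 comparisons by limma. The other splits leave any treatment difference within the groups, which widens the residual spread and lowers their counts. In gene lists called, 2 splits reached the 10 lists of CPI203 (highest other 10), 3 the 9 lists of IRAKi (highest other 11), 4 the 8 lists of Combo (highest other 10), 3 the 4 lists of Combo against CPI203 (highest other 6) and 3 the 7 lists of Combo against IRAKi (highest other 10). Among the 3 other splits that exchange treatments within lines as the real one does, the highest counts of lists were 8, 7, 10, 2 and 7, which reach the real count for Combo against Control and Combo against IRAKi.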

How the results depend on the processing

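The fit without the OCI-LY10 IRAKi array and the scaling to poly-A spike-ins were chosen after seeing the data. Over all alternatives, the counts of genes were within 1.5 times the reported ones in 57 cases and moved further in 44. Every probe set on its own gave 3134 (CPI203), 8817 (Combo), 1038 (Combo against CPI203) and 4778 (Combo against IRAKi), because more probe sets were tested, and 0 for the interaction term. Without the cell line in the model the counts were 4 (CPI203), 0 (IRAKi, with 295 at an unadjusted p below 0.05 in limma), 465 (Combo), 2 (Combo against CPI203), 7 (Combo against IRAKi) and 0 (interaction term, 146 unadjusted). At least 2-fold changes left 380, 12, 1244, 135 and 563 in the 5 comparisons, by construction. For IRAKi the mean of probe sets gave 13, the stricter filter 66, trend and robust estimation 220, a random block 11, only the 2 groups 0 (1995 unadjusted) and leaving out the OCI-LY10 IRAKi array 0 (1601 unadjusted). Only the 2 groups gave 2163 (Combo), 198 (Combo against CPI203) and 977 (Combo against IRAKi), and trend and robust estimation 954 for Combo against CPI203. Without the OCI-LY10 IRAKi array the count was 1487 for Combo against IRAKi and 0 for the interaction term (1051 unadjusted). With 1 line left out, counts ranged from 216 to 720 (CPI203), 0 to 0 (IRAKi), 2072 to 3420 (Combo), 0 to 3 (Combo against CPI203), 526 to 1704 (Combo against IRAKi) and 0 to 0 (interaction term), in fits with fewer arrays. Except where fewer arrays, more probe sets or a fold threshold account for it, the cause was not tested.

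NF-kB targets kept their direction and stayed uncalled in 76 cases. In Combo against Control the median was -0.131 without OCI-LY3, -0.243 without OCI-HBL1 and -0.223 without OCI-LY10. In Combo against CPI203 the median turned to 0.0683 with median centring, and ranged from -0.0723 to 0.0457 with 1 line left out. In Combo against IRAKi it ranged from -0.398 to 0.0693, positive without OCI-LY3, and with IRAKi against Control from -0.157, called without OCI-LY3, to -0.00461. For the Combo comparisons the cause was not tested.

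Of the 38 other list calls, each was lost with an estimated correlation, 9 without the cell line in the model, 4 with a random block, and 3, 1 and 5 without OCI-LY3, OCI-HBL1 and OCI-LY10. Without the OCI-LY10 IRAKi array 1 was lost. The JAK-STAT3 and immediate early lists with CPI203 were lost with the stricter filter (adjusted p = 0.073 and 0.0707) and with trend and robust estimation (0.0609 and 0.066). The plasma cell list with IRAKi was lost with median centring (0.051), only the 2 groups (0.0552) and spike-in scaling (0.0785). Scaled to the spike-ins, the immediate early list's median turned to -0.0876 with CPI203 and -0.00729 with Combo, while camera, which compares with other genes, still called it higher. Of 217 called results of named genes, 97, 70 and 102 were no longer called without OCI-LY3, OCI-HBL1 and OCI-LY10, and 192 without the cell line in the model. Of 17 printed results of named genes that did not pass, 9 passed in at least 1 alternative, 11 cases in all, among them MYC with CPI203 under array weights and under spike-in scaling. ODC1 and SLBP in Combo against Control turned to -0.189 and -0.143 with spike-in scaling, which shifts every gene down.

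The correlation of the CPI203 effect with and without IRAKi was 0.806 with the stricter filter and 0.693 to 0.734 with 1 line left out. That of the IRAKi effect with and without CPI203 was 0.442 with no filter, 0.559 with the stricter filter and 0.396 to 0.457 with 1 line left out, and the cause was not tested. Signal over background limits the 5119 genes below the filter, which the reported comparisons leave out and the alternative with no filter tested.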

Other observations

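The gene families below were chosen only after the results were seen, from 157 groups of genes that share a symbol stem, and none holds with an estimated correlation (lowest adjusted p = 0.838).

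Genes of the mitochondrial ribosome were lower with Combo than in Control. Of 48 large-subunit genes (MRPL) 31 fell and 1 rose (median log2 change -0.46, adjusted p = 5.6e-08), and of 28 small-subunit genes (MRPS) 19 fell and none rose (median -0.44, adjusted p = 2.8e-06). The medians with the single treatments were -0.23 and -0.15 with CPI203 and -0.15 and -0.16 with IRAKi. Genes of the RNA exosome (EXOSC), which degrades and trims nuclear RNA, were lower as well, with 8 of 10 fallen and none risen with Combo (median -0.66, adjusted p = 0.00011). These directions were the same with median centring, cyclic loess and spike-in scaling. The last shifts the median gene down, by -0.487 with Combo, so it could not have turned these falls.

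Splicing factor genes of the SRSF family had medians of 0.02 with CPI203 and -0.39 with IRAKi, a difference that was not tested. In Combo against CPI203, 6 of 11 members fell and none rose (median -0.55, adjusted p = 1.9e-05), and in Combo against Control 6 fell (median -0.52, adjusted p = 0.04). The direction was the same with median centring and cyclic loess, except with CPI203 alone, where the median was -0.0053 with cyclic loess. With spike-in scaling the median with CPI203 was -0.29, beside a shift of -0.298 for the median gene. The falls kept their direction under spike-in scaling, which could not have turned them, as it shifts the median gene down.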
